A study of Rattus norvegicus with 40 samples.

How the data were processed

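Gene expression was measured in 40 arrays of the rat insulin-producing line INS-1E, labelled INS1, on Affymetrix Rat ST arrays hybridised with biotin-labelled total RNA. The cells had been cultured in medium alone (15 arrays) or with recombinant human IL-1 at 10 units/ml and recombinant murine IFN-γ at 100 units/ml (25 arrays). A treatment characteristic of some arrays names IFN-beta beside IFN-γ, whereas the titles, the treatment protocol and the design text name IL-1 and IFN-γ, and the latter were followed. The extraction protocol speaks of islets, while every sample is labelled as the cell line. Arrays were grouped by treatment and by 13 times from 0 to 72 h, as the titles give them, into 26 groups, of which 14 hold 2 arrays and 12 hold 1.

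The deposited table holds log2 signal values, 1 per probe set and array, and was used as deposited. That the scale is log2 was read from the values, which run from 2.27 to 14.46; background correction, summarisation and normalization are not given in the sources used here. Array medians lay between 6.54 and 6.62, 25th percentiles between 4.83 and 5.10 and 75th percentiles between 8.19 and 8.33, so the arrays had been brought to a similar scale. Pairwise correlations of arrays across probe sets lay between 0.971 and 0.996, and 0 arrays held values identical to another. Each value column matched the labels of 1 sample. The number of arrays limits the precision. The series states that the experiments were done on 2 separate occasions, but the labels do not tie a replicate number to an occasion, nor say that replicates came from separate cultures. The p-values therefore measure the spread between these arrays, which may be technical.

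Of 19239 probe sets, 16592 carried 1 gene symbol in the platform annotation, 0 carried several and 2647 were unnamed. Probe set identifiers are a gene number followed by _at. Of these numbers, 16453 were found in a gene table of the rat assembly GRCr8, which was used for names only: 13094 symbols were identical, 3326 were synonyms and were updated, and 33 conflicted and were kept as annotated. For 5 symbols with several probe sets, the brightest by its mean over all 40 arrays was used, which left 16587 symbols. No filter on dim probe sets was applied. Transcripts of near-identical families (the RT1, Gbp, Ifit, Oas and Mx genes) may hybridise to each other's probes, so values of single members are uncertain. Some genes of the fixed lists are not reported here.

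Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, statmod 1.5.0 for array weights and robust moderation) on log2 values. A model with 1 coefficient per group was fitted to all 40 arrays, with 14 residual and 6.05 prior degrees of freedom, because most control times have 1 array. A lone array was thus assumed to vary like the groups that have 2. The comparisons were cytokine minus control at 0 h and averaged over an early window (1, 2 and 4 h), an intermediate window (6, 8, 10 and 12 h) and a late window (24, 36, 48, 60 and 72 h), each time weighted equally. The late minus the early difference, and control arrays at the late times against control arrays at 0 h, were tested too. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over the 16587 symbols of a comparison, and the number that also differed at least 2-fold was counted. Means and SDs of levels are over the arrays of a window, so the SD includes change between its times, and a window's log2 difference can depart slightly from the difference of its means. The windows use different control arrays and share only the estimate of the spread.

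A total of 29 gene lists was fixed before the data were examined, as were the windows, the tests, the alternatives and the rule for named genes. Lists were tested with camera in limma at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 29 lists of a comparison, then with an estimated correlation and with fry. camera compares a list with the other genes, whereas fry asks whether the genes of the list move on balance one way. Called members were counted after adjustment over all genes and adjusted over the list alone. The named genes were, per window, the 15 largest positive and 10 largest negative differences among called genes with the same sign at every time of the window, up to 4 members of each list with the smallest p, and the 6 largest called values in each direction of the other comparisons. Nos2, Ins1, Ins2, Ddit3, Irf1, Nfkbia, Cxcl10, Ccl2, Sod2, Mafa and Slc2a2 were always included. Single times are given as values, without calls.

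The alternatives were the replicate number as a block, quantile normalization, arrays centred on their medians, the third of genes with the lowest mean left out, the mean of all probe sets of a symbol, eBayes with trend and robust moderation, array weights, an additive model on the arrays of a comparison only, the same on replicate 1 arrays only, and each array left out in turn. For lists, camera has no robust option, so only its variance trend was used, and arrays were not left out. Leaving out 4 h or 36 h was added after seeing the data. Leaving out the lone control array of a time removes that time from the window. The fit was tested on simulated data with the real design and 16587 genes, of which 100 per size were changed. The simulated noise was independent and normal with the fit's own variances, and each change was constant at all cytokine times after 0 h. The shares called thus do not cover replicate effects, correlated genes or genes that change at only some times. A log2 change of 0.5 was called for 71% of the changed genes in the early, 72% in the intermediate and 89% in the late window, and a log2 change of 1 for 100% in each. In the same windows 7, 11 and 12 unchanged genes were called. Unnamed probe sets were left out of the comparisons and of the adjustment, and 0 value columns were unused.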

Results

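INS-1E cells, a line derived from a rat insulinoma that makes and secretes insulin, were profiled at 13 times between 0 and 72 h of culture in medium alone or with IL-1 and IFN-γ, inflammatory cytokines used to model immune damage to beta cells. There were 15 control arrays, with 2 at 0 and 1 h and 1 at each of the other 11 times, and 25 cytokine arrays, with 2 at 12 times and 1 at 10 h. The values are log2 signals of 16587 genes. The first principal component held 33.1% of the variance. On it the control arrays stayed between -19.2 and -15.4 at all times, while the cytokine arrays reached 29.8 at 10 h. On the second component (12.5% of the variance) the control arrays did change with time. They lay between 2.53 and 10.6 from 1 to 12 h and between -11.3 and -1.64 at the late times. The control arrays at 0 h lay at 8.68 (replicate 1) and -2.42 (replicate 2).

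**Figure D1:**
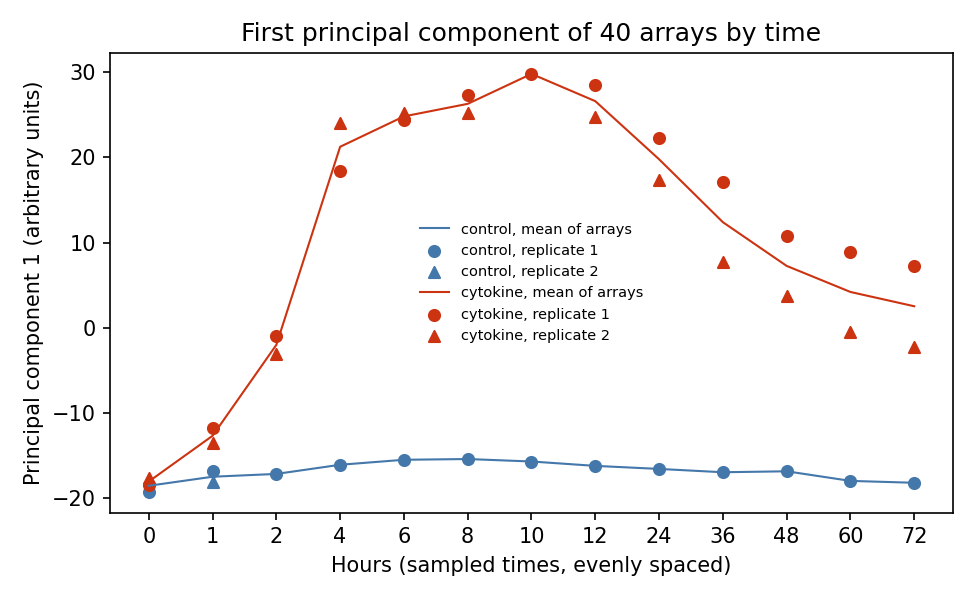
First principal component (arbitrary units) of the 40 arrays against the sampled times in hours, evenly spaced, with circles for replicate 1, triangles for replicate 2 and lines through group means. Control arrays lie between -19.2 and -15.4, and cytokine arrays are highest at 10 h, at 29.8.

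Cytokine and control arrays at 0 h (2 against 2) gave the background of the design. Both arms hold both replicate numbers at 0 h, whereas every control array after 1 h is replicate 1. This background therefore does not cover a replicate effect in the windows. Irf1, a transcription factor gene induced by interferon, differed by 0.03 (SE 0.33) on the log2 scale. Ins2, one of the rat insulin genes, differed by 0.08 (SE 0.12) and Nos2, the inducible nitric oxide synthase, by -0.41 (SE 0.45). limma with Benjamini-Hochberg adjustment called 0 genes, with a smallest adjusted p of 0.999, and 556 genes had an unadjusted p under 0.05. Of the 29 lists, camera and fry each called 0. Without control 0 h replicate 2, 92 genes were called, 57 higher and 35 lower.

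In the early window (1, 2 and 4 h) genes that respond to interferon and to NF-kB were higher with cytokines. Irf1 (probe set 24508_at) rose 18.9-fold, from 6.83 ± 0.18 (SD, n = 4) in control arrays to 11.06 ± 0.48 (SD, n = 6) with cytokines (log2 4.24, SE 0.22, limma adjusted p = 3.6e-11). The interferon-inducible GTPase gene Igtp rose 16.7-fold, and Tap1, which encodes a subunit of the peptide transporter for MHC class I, 9.63-fold. Cxcl1, a chemokine that attracts neutrophils, rose 15.2-fold (adjusted p = 2.09e-13). Cxcl10, a chemokine that attracts T cells, rose 13.4-fold, from 7.29 ± 0.15 (SD, n = 4) to 11.02 ± 1.26 (SD, n = 6, limma adjusted p = 1.84e-13). Nfkbia, the inhibitor that NF-kB itself induces, rose 2.95-fold (adjusted p = 2.24e-11). At 1 h the log2 differences of Irf1 and Cxcl1 already stood at 3.81 and 3.22, while that of Nos2 was 0.10 at 1 h, 0.19 at 2 h and 3.26 at 4 h.

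In this window 247 genes were called, 239 higher and 8 lower, and 87 of the higher ones by at least 2-fold. The additive model on these arrays called 45 genes, and replicate 1 arrays alone 20. With the replicate number as a block 292 were higher and 26 lower. Without the control 4 h array, and so without 4 h, which was also added as an alternative after seeing the data, 96 genes were called, 90 higher and 6 lower, 50 of them at least 2-fold. The count of lower genes was 79 without control 1 h replicate 2, 21 without cytokine 4 h replicate 1, and 5 without control 1 h replicate 1, control 2 h, cytokine 1 h replicate 1 or cytokine 2 h replicate 2. Nos2 was called at a log2 difference of 1.18 (SE 0.30, adjusted p = 0.0495). This call did not pass without control 4 h (adjusted p = 0.943), control 1 h replicate 2 (0.0984), cytokine 1 h replicate 1 (0.128) or 2 (0.0677), cytokine 2 h replicate 1 (0.145) or cytokine 4 h replicate 2 (0.174). Nor did it pass with trend and robust moderation (0.121), array weights (0.0757), the additive model (0.753) or replicate 1 arrays alone (0.977). Ccl2, a monocyte chemokine gene, rose by 1.27 (adjusted p = 5.24e-06) and Sod2, the mitochondrial superoxide dismutase, by 0.76 (adjusted p = 0.000422). Both calls were lost without control 4 h (adjusted p = 0.117 and 0.114), in the additive model (0.453 and 0.062) and with replicate 1 arrays alone (0.554 and 0.197). Among the lower genes, Matn3, a matrix protein gene, at -0.35, and Ice1, a transcription elongation gene, at -0.34, were not called without control 2 h (adjusted p = 0.315 and 0.131) or control 4 h (0.131 and 0.285). Matn3 was also not called without cytokine 1 h replicate 1 (0.0542) or with quantile normalization (0.0897), and neither was called in the additive model (0.394 and 0.409) or with replicate 1 arrays alone (0.782 and 0.956).

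By list, 24 of 42 interferon targets rose in the early window (30 adjusted over the list alone), with a median log2 difference of 0.97 (camera adjusted p = 6.9e-70). Genes of MHC class I antigen processing rose in 10 of 17 cases (14 adjusted over the list alone, camera adjusted p = 2.97e-33). Chemokines and cytokines rose in 14 of 34 (17 alone, 1.62e-32) and NF-kB targets in 11 of 23 (14 higher and 1 lower alone, 1.16e-26). Csf1, a macrophage growth factor gene that stands on both of these lists, rose 5.02-fold. The list of cytokine receptors and signal relays was shifted up with 6 of 25 members higher (10 alone, 2.23e-09), and that of feedback regulators with 3 of 25 (3 alone, 1.94e-05). Zfp36, a feedback gene whose product destabilises cytokine mRNAs, rose by 1.66. Immediate early genes (6 of 24 higher, 8 alone, 4.44e-06) and apoptosis regulators (6 of 36 higher, 8 alone, 0.000474) were also shifted up. The death receptor gene Fas rose by 1.40, a call lost with replicate 1 arrays alone (adjusted p = 0.171). The member of this list with the smallest p was Birc3, an inhibitor of apoptosis gene that is also on the NF-kB list. It differed by 0.34 at 1 h, 1.64 at 2 h and 1.98 at 4 h. The apoptosis list had a median of -0.02 beside a mean of 0.18. All 8 of these list calls held with an estimated correlation.

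Other early list calls were lost with an estimated correlation. p53 targets were shifted up (3 of 21 higher, 4 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.013), with adjusted p = 0.336 with an estimated correlation. Antioxidant defence (2 of 25 higher, 2 alone, 0.0435) and ER chaperones and ER-associated degradation (1 of 34 higher, 1 alone, 0.00365) were shifted up, each with adjusted p = 0.695 with an estimated correlation. The proteasome was shifted up (camera adjusted p = 0.00181, adjusted p = 0.423 with an estimated correlation) while limma called 0 of 33 members, 0 adjusted over the list alone and 3 at an unadjusted p under 0.05. Beta cell identity and function was shifted down (camera adjusted p = 0.013, adjusted p = 0.695 with an estimated correlation). Of its 34 members limma called 0, with 7 at an unadjusted p under 0.05 and 1 lower adjusted over the list alone. Here Ins1 differed by 0.04 (adjusted p = 0.955), Ins2 by 0.06 (0.883), the beta cell transcription factor gene Mafa by -0.17 and the glucose transporter gene Slc2a2 by -0.08. Without 4 h the value of Slc2a2 was 0.03.

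The remaining early lists were not shifted by camera. MHC class II had 0 of 12 members called by limma (0 adjusted over the list alone, 0 at an unadjusted p under 0.05, camera adjusted p = 0.908). Cd74, the invariant chain of MHC class II, differed by 0.47 (adjusted p = 0.758). ATF4 and CHOP targets rose in 2 of 34 cases (2 alone, camera adjusted p = 0.116), and genes of nitric oxide and arginine metabolism in 1 of 18 (1 alone, 0.641). Glycolysis genes rose in 3 of 21 (3 alone, 0.166) and type 1 diabetes candidate genes in 1 of 15 (1 alone, 0.908). That candidate was Ifih1, a viral RNA sensor gene, at 0.57 (adjusted p = 0.0387), with -0.05 and an adjusted p of 0.963 without control 4 h. It was also not called without control 1 h replicate 1 (0.104) or any 1 of the 6 early cytokine arrays (0.0732 to 0.0909), with array weights (0.0751), in the additive model (0.812) or with replicate 1 arrays alone (1). In 11 other lists limma called 0 members. Of these, oxidative phosphorylation had 50 measured members, 1 of them at an unadjusted p under 0.05, and a camera adjusted p of 0.0504. In the same order the values were 30, 2 and 0.572 for the TCA cycle, 21, 0 and 0.64 for cholesterol synthesis, and 40, 1 and 0.862 for the cell cycle. They were 39, 1 and 0.908 for the secretory granule, 16, 0 and 0.908 for heat shock proteins, 43, 3 and 0.98 for splicing regulators, and 28, 1 and 0.5 for ion channels. For markers of other cells they were 22, 2 and 0.166 for leukocytes, 28, 2 and 0.252 for endothelial, stromal, acinar and duct cells, and 12, 0 and 0.908 for other islet hormones. Adjusted over the list alone, 1 leukocyte marker was lower and 0 members of the other 10 lists passed. The median differed in sign from the mean or the test for MHC class II, nitric oxide, secretory granule, glycolysis and type 1 diabetes genes.

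**Figure D2:**
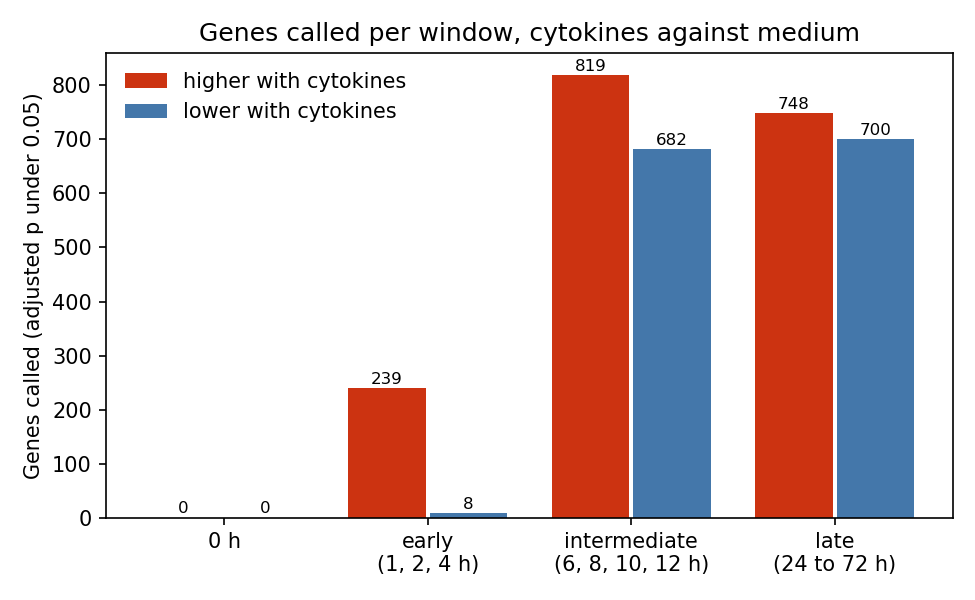
Number of genes called by limma at an adjusted p under 0.05 (vertical axis) at 0 h and in the early, intermediate and late windows, split into higher and lower with cytokines. The early window holds 239 higher and 8 lower genes, the intermediate window 819 and 682, and the late window 748 and 700.

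In the intermediate window (6 to 12 h) Mx2 (probe set 286918_at), an interferon-induced antiviral GTPase gene, rose 86.2-fold, from 5.21 ± 0.15 (SD, n = 4) to 11.60 ± 0.32 (SD, n = 7, log2 6.43, SE 0.37, limma adjusted p = 5.12e-11), and Gbp2 rose 51.9-fold. Nos2 (probe set 24599_at) rose 15.1-fold, from 6.17 ± 0.18 (SD, n = 4) to 10.06 ± 0.25 (SD, n = 7, log2 3.92, SE 0.28, limma adjusted p = 2.2e-09). Cd74 rose 21.3-fold, Cxcl10 24.8-fold and Usp18, a negative regulator of interferon signalling, 22.2-fold, and Sod2 rose by 1.22 on the log2 scale. Car8, a carbonic anhydrase-related protein gene, fell by 1.65 (SE 0.23, adjusted p = 2.54e-05) and Aadat, an enzyme of tryptophan and lysine breakdown, fell by 1.47.

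In this window 1501 genes were called, 819 higher and 682 lower, of which 223 and 8 by at least 2-fold. Replicate 1 arrays alone gave 988, 637 higher and 351 lower. With the replicate number as a block 931 were higher and 1034 lower. Without control 12 h 681 were higher and 346 lower (234 and 5 at least 2-fold), and without control 8 h 666 and 415. Of the 239 genes higher early, 208 were also higher here, against 11.8 expected for independent lists of these sizes, and of the 8 lower ones 4 were lower here (0.329 expected). The windows are not independent, however. They share the estimate of each gene's spread and a replicate number partly tied to treatment, both of which favour overlap. The excess over the expected numbers therefore does not gauge chance.

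Genes of antigen processing and of the interferon response were raised together at 6 to 12 h. Of MHC class I processing genes 17 of 17 rose (17 adjusted over the list alone), with a median of 2.06 (camera adjusted p = 1.39e-50). Among them B2m, the MHC class I light chain, rose by 3.15 and the immunoproteasome subunit gene Psmb9 by 4.30. Interferon targets rose in 37 of 42 cases (40 alone, median 2.55, 1.34e-93). MHC class II rose in 8 of 12 members (8 alone, 1.66e-10), including its transactivator gene Ciita by 0.99 and RT1-Da by 3.30. Leukocyte markers, of a cell type that carries MHC class II, had 1 of 22 members higher and 1 lower (1 and 1 alone, camera adjusted p = 0.672). NF-kB targets (15 of 23 higher, 16 higher and 1 lower alone, 2.71e-26) and chemokines and cytokines (19 of 34 higher, 19 alone, 2.6e-28) were shifted up. So were receptors and relays (8 of 25 higher, 10 higher and 2 lower alone, 1.39e-06) and feedback regulators (4 of 25 higher, 5 alone, 0.001). Apoptosis regulators rose in 11 of 36 members (11 alone, 8.44e-08), among them Fas by 2.05, the necroptosis effector gene Mlkl by 2.46 and the pyroptosis effector gene Gsdmd by 1.43. The inhibitor of apoptosis gene Birc3 again had the smallest p of this list, with differences of 2.31 at 6 h and 2.45 at 12 h. All 8 of these list calls held with an estimated correlation.

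Other intermediate list calls were lost with an estimated correlation. p53 targets were shifted up (6 of 21 higher and 2 lower, 7 and 2 adjusted over the list alone, camera adjusted p = 0.00235), with adjusted p = 0.178 with an estimated correlation. In this list Cdkn1a, a cell cycle inhibitor gene, rose by 1.43. ATF4 and CHOP targets were shifted up (7 of 34 higher and 1 lower, 9 and 2 alone, camera adjusted p = 0.00235), with adjusted p = 0.4 with an estimated correlation. Ddit3, which encodes the stress transcription factor CHOP, rose by 0.66 (adjusted p = 0.00143, and 0.0768 with replicate 1 arrays alone). Beta cell identity and function was shifted down (1 of 34 higher and 8 lower, 1 and 8 alone, camera adjusted p = 0.0206), with adjusted p = 0.678 with an estimated correlation. Slc30a8, the zinc transporter gene of insulin granules, fell by 0.55 (adjusted p = 0.00134). Slc2a2 fell by 0.29 (adjusted p = 0.00454, and 0.0671 with replicate 1 arrays alone), and Ins1 and Ins2 differed by -0.09 (adjusted p = 0.703) and -0.08 (0.65). The TCA cycle list was shifted down (1 of 30 higher and 5 lower, 2 and 7 alone, camera adjusted p = 0.00702), with adjusted p = 0.4 with an estimated correlation. Gpd2, the mitochondrial glycerophosphate dehydrogenase gene, fell by 0.54. Oxidative phosphorylation was shifted down (camera adjusted p = 0.0314, adjusted p = 0.678 with an estimated correlation), while limma called 0 of 50 members, 0 alone and 6 at an unadjusted p under 0.05. The cell cycle list was shifted down with 1 of 40 lower (0 alone, camera adjusted p = 0.00792, adjusted p = 0.583 with an estimated correlation).

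The other intermediate lists were not shifted by camera. Glycolysis had 2 of 21 members higher and 2 lower (2 and 4 adjusted over the list alone, camera adjusted p = 0.762), with the phosphofructokinase gene Pfkp up by 2.05. The proteasome had 6 of 33 higher (9 alone, 0.137), with Psma7 up by 0.54. The secretory granule list had 2 of 39 higher and 5 lower (2 and 5 alone, 0.0631), and Sytl4, a granule docking protein gene, fell by 0.69. Immediate early genes had 4 of 24 higher and 4 lower (6 and 5 alone, 0.2), with the transcription factor gene Junb at 0.93 and the nuclear receptor gene Nr4a1 at -1.04. Nitric oxide and arginine metabolism had 2 of 18 higher (4 alone, 0.595), and antioxidant defence 3 of 25 higher and 1 lower (3 and 3 alone, 0.901). ER chaperones had 2 of 34 higher and 1 lower (2 and 1 alone, 0.897), and type 1 diabetes candidates 2 of 15 higher (2 alone, 0.0523). Ion channels had 2 of 28 higher and 1 lower (2 and 2 alone, 0.582), and splicing regulators 2 of 43 higher (2 alone, 0.765). Heat shock proteins had 1 of 16 higher (1 alone, 0.672) and cholesterol synthesis 1 of 21 lower (1 alone, 0.672). Other islet hormones had 1 of 12 lower (1 alone, 0.788), the glucagon gene Gcg, at -0.69 (adjusted p = 0.00699, and 0.0532 without control 12 h). Endothelial, stromal, acinar and duct markers had 1 of 28 higher and 1 lower (1 and 1 alone, 0.897). Median, mean and test were not all of one sign for nitric oxide, antioxidant, ER chaperone, other islet hormone, endothelial and stromal, glycolysis and proteasome genes.

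**Figure D3:**
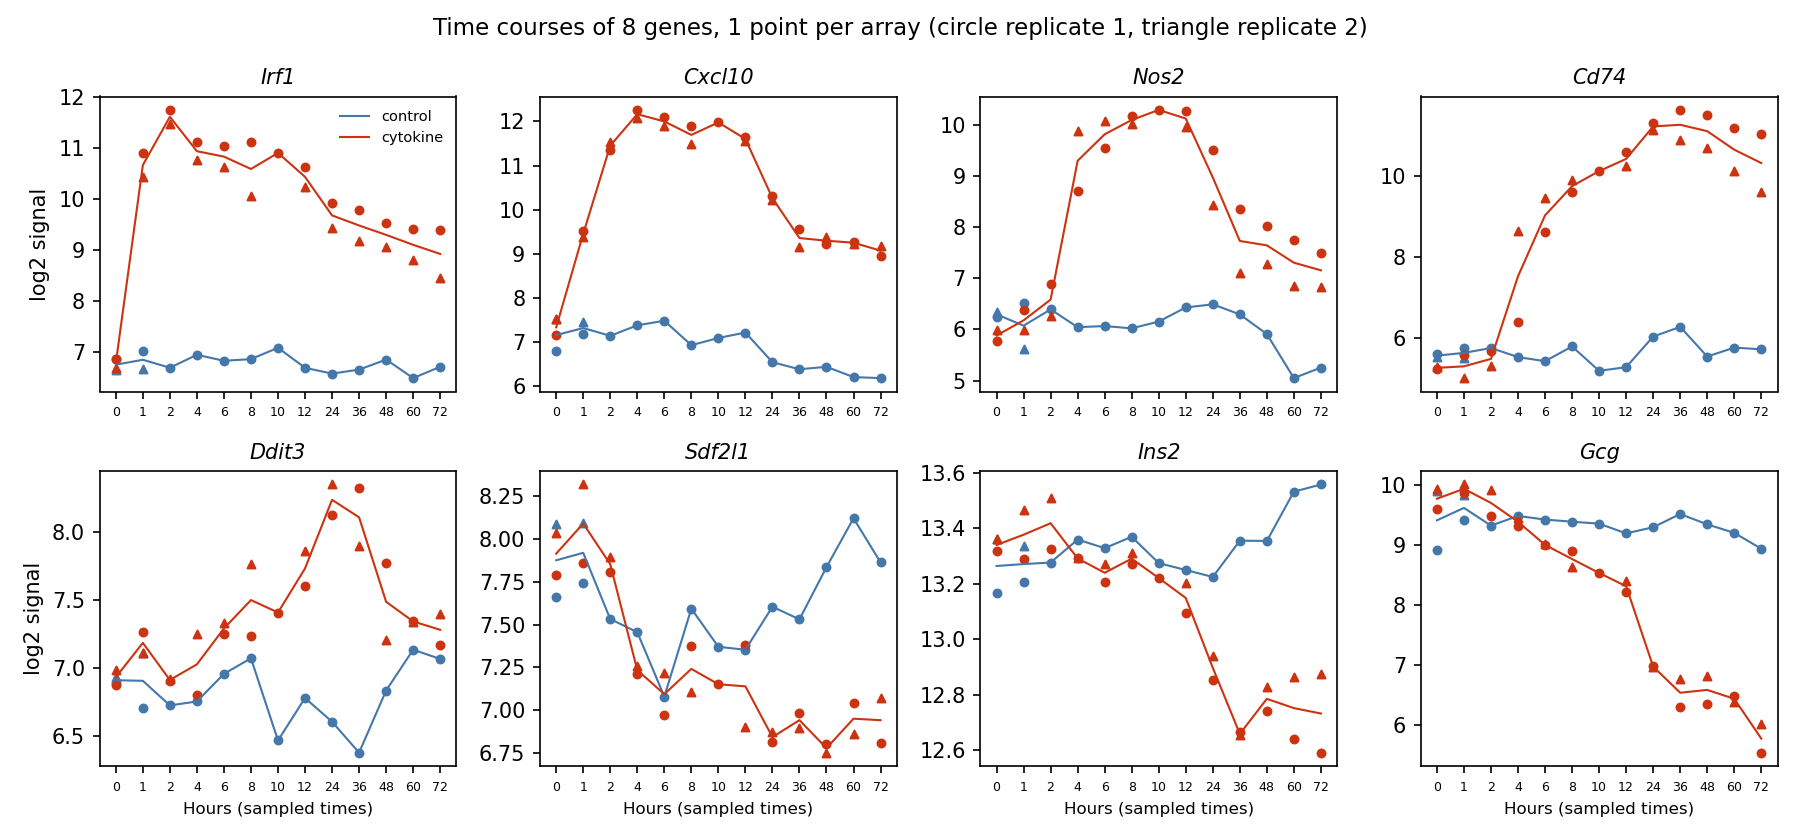
Log2 signal of Irf1, Cxcl10, Nos2, Cd74, Ddit3, Sdf2l1, Ins2 and Gcg against the sampled times in hours, evenly spaced, with 1 point per array (circles replicate 1, triangles replicate 2) and lines through group means of control and cytokine arrays. Irf1 already differs by 3.81 at 1 h, Nos2 by 3.26 at 4 h, Ddit3 by 1.73 at 36 h and Gcg by -3.17 at 72 h.

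In the late window (24 to 72 h) antigen presentation genes were high, while cell cycle genes and the hormone genes Gcg and Ins2 were lower than in control arrays. Cd74 (probe set 25599_at) rose 33.2-fold, from 5.86 ± 0.29 (SD, n = 5) to 10.91 ± 0.63 (SD, n = 10, log2 5.05, SE 0.29, limma adjusted p = 1.22e-10), and B2m rose 9.03-fold. Gcg (probe set 24952_at) fell by 2.80 on the log2 scale (SE 0.138, limma adjusted p = 9.27e-12), from 9.26 ± 0.21 (SD, n = 5) to 6.46 ± 0.45 (SD, n = 10). Ins2 (probe set 24506_at) fell by 0.64 (SE 0.065, limma adjusted p = 6.75e-07), from 13.41 ± 0.14 (SD, n = 5) to 12.76 ± 0.12 (SD, n = 10). Pcsk1, the convertase gene for proinsulin processing, fell by 1.18 (adjusted p = 3.85e-06). Igf1, an insulin-like growth factor gene, fell by 1.67, the neuropeptide gene Npy fell by 1.42, and Enpp2, which encodes the secreted enzyme autotaxin, fell by 1.57.

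In this window 1448 genes were called, 748 higher and 700 lower, of which 134 and 16 by at least 2-fold. With the replicate number as a block 837 were higher and 943 lower. Without control 36 h, and so without 36 h, which was also added as an alternative after seeing the data, 581 were higher and 403 lower, and without control 24 h 545 and 432. Of the genes called in the intermediate window, 433 of the higher (36.9 expected for independent lists) and 176 of the lower (28.8 expected) were called in the same direction here. Of those called early, 163 higher (10.8 expected) and 2 lower (0.338 expected) were. These expected numbers have the same limit as those for the intermediate window, since the windows are not independent. Ins1 fell by 0.30 (adjusted p = 0.0309), with cytokine 36 h replicate 2 low at 13.49 and the other late cytokine arrays at 13.94 to 14.21. This call did not pass with quantile normalization (adjusted p = 1), which gives the same value to the brightest probe set of every array, as Ins1 was on all 40. It also did not pass with the replicate number as a block, with the additive model (0.0636) or with replicate 1 arrays alone (0.0914). The call was lost as well without control 36 h (0.177), 48 h (0.057), 60 h (0.0661) or 72 h (0.0568), cytokine 60 h replicate 2 (0.0538) or cytokine 72 h replicate 2 (0.0601). Mafa (-0.10, adjusted p = 0.683), Slc2a2 (0.06, adjusted p = 0.576) and Ccl2 (-0.03, adjusted p = 0.934) were not called, and the sign of Ccl2 turned with quantile normalization (0.02) and without control 72 h (0.03).

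Immune lists were shifted up at 24 to 72 h as well. MHC class I processing genes rose in 15 of 17 cases (16 adjusted over the list alone, median 1.68, camera adjusted p = 1.11e-47). MHC class II genes rose in 9 of 12 (9 alone, 1.73e-12), including RT1-Da by 3.32 and RT1-Ba by 1.86, and interferon targets in 32 of 42 (34 alone, median 1.18, 4.56e-53). Leukocyte markers had 0 of 22 called by limma (0 alone, 3 at an unadjusted p under 0.05, median -0.08, camera adjusted p = 0.297). NF-kB targets (12 of 23 higher and 1 lower, 16 and 1 alone, 8.54e-17) and chemokines and cytokines (10 of 34 higher and 2 lower, 11 and 2 alone, 3.66e-07) were shifted up. So were receptors and relays (6 of 25 higher, 8 higher and 1 lower alone, 0.0012) and apoptosis regulators (9 of 36 higher and 1 lower, 12 and 1 alone, 0.000623). The inflammatory caspase gene Casp4 rose by 1.95 and Mlkl by 1.62, and the apoptosis list had a median of -0.02 beside a mean of 0.21. Its member with the smallest p was the inhibitor of apoptosis gene Birc3, which differed by 2.26 at 24 h and 1.67 at 72 h.

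The cell cycle list was shifted down, with 20 of 40 genes lower (26 adjusted over the list alone, median -0.38, camera adjusted p = 4.75e-14). At single times its median was -0.54 at 36 h and -0.08 at 72 h. Top2a, the mitotic topoisomerase gene, fell by 0.62 and the cyclin gene Ccna2 fell by 0.54. These 8 late list calls held with an estimated correlation. Stress-related lists went in opposite directions on average over the window. ATF4 and CHOP targets were shifted up with 12 of 34 higher (13 alone, median 0.17, camera adjusted p = 6.44e-09), with adjusted p = 0.0615 with an estimated correlation. Trib3, a pseudokinase gene induced by CHOP, rose by 1.07 and Ddit3 by 0.89 (adjusted p = 1.02e-05, and 0.0696 with replicate 1 arrays alone). ER chaperones and ER-associated degradation were shifted down with 1 of 34 higher and 14 lower (2 and 16 alone, median -0.18, camera adjusted p = 1.97e-05), with adjusted p = 0.468 with an estimated correlation. Sdf2l1, a chaperone cofactor gene, fell by 0.90 (adjusted p = 2.23e-06) and Derl3, a degradation factor gene, fell by 0.97, whereas the calcium pump gene Atp2a3 rose by 0.99. Antioxidant defence was shifted up (3 of 25 higher, 3 alone, camera adjusted p = 0.0288), with the heme oxygenase gene Hmox1 up by 0.77 and adjusted p = 0.609 with an estimated correlation. Oxidative phosphorylation was shifted down (2 of 50 lower, 2 alone, camera adjusted p = 0.0468), with adjusted p = 0.707 with an estimated correlation.

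The remaining late lists were not shifted by camera. Beta cell identity and function had 3 of 34 higher and 8 lower (3 and 10 adjusted over the list alone, camera adjusted p = 0.297). The secretory granule had 3 of 39 higher and 8 lower (4 and 9 alone, 0.894), with the granule peptide gene Vgf at -0.52. Nitric oxide and arginine metabolism had 3 of 18 higher and 4 lower (4 and 5 alone, 0.329), with Nos2 up by 1.96 and Ass1, which regenerates arginine, up by 0.89. Feedback regulators had 4 of 25 higher and 1 lower (4 and 1 alone, 0.0946), and immediate early genes 5 of 24 higher and 2 lower (5 and 3 alone, 0.302). p53 targets had 3 of 21 higher and 2 lower (3 and 2 alone, 0.0946), and the TCA cycle 5 of 30 lower (5 alone, 0.0792), with Gpd2 at -0.40. Other islet hormones had 1 of 12 higher and 1 lower (1 and 1 alone, 0.845). Endothelial, stromal, acinar and duct markers had 1 of 28 higher and 2 lower (1 and 2 alone, 0.837), and the acinar gene Ctrb1 fell by 0.76. Ion channels had 4 of 28 higher and 4 lower (4 and 5 alone, 0.364), and type 1 diabetes candidates 3 of 15 higher and 1 lower (3 and 1 alone, 0.579). Cholesterol synthesis had 1 of 21 higher and 2 lower (1 and 2 alone, 0.393), and the proteasome 3 of 33 higher and 1 lower (3 and 1 alone, 0.99). Glycolysis had 1 of 21 higher and 1 lower (2 and 1 alone, 0.826), heat shock proteins 2 of 16 higher (2 alone, 0.302) and splicing regulators 1 of 43 lower (1 alone, 0.826). Median, mean and test were not all of one sign for feedback, immediate early, nitric oxide, other islet hormone, glycolysis, proteasome, heat shock and type 1 diabetes genes.

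**Figure D4:**
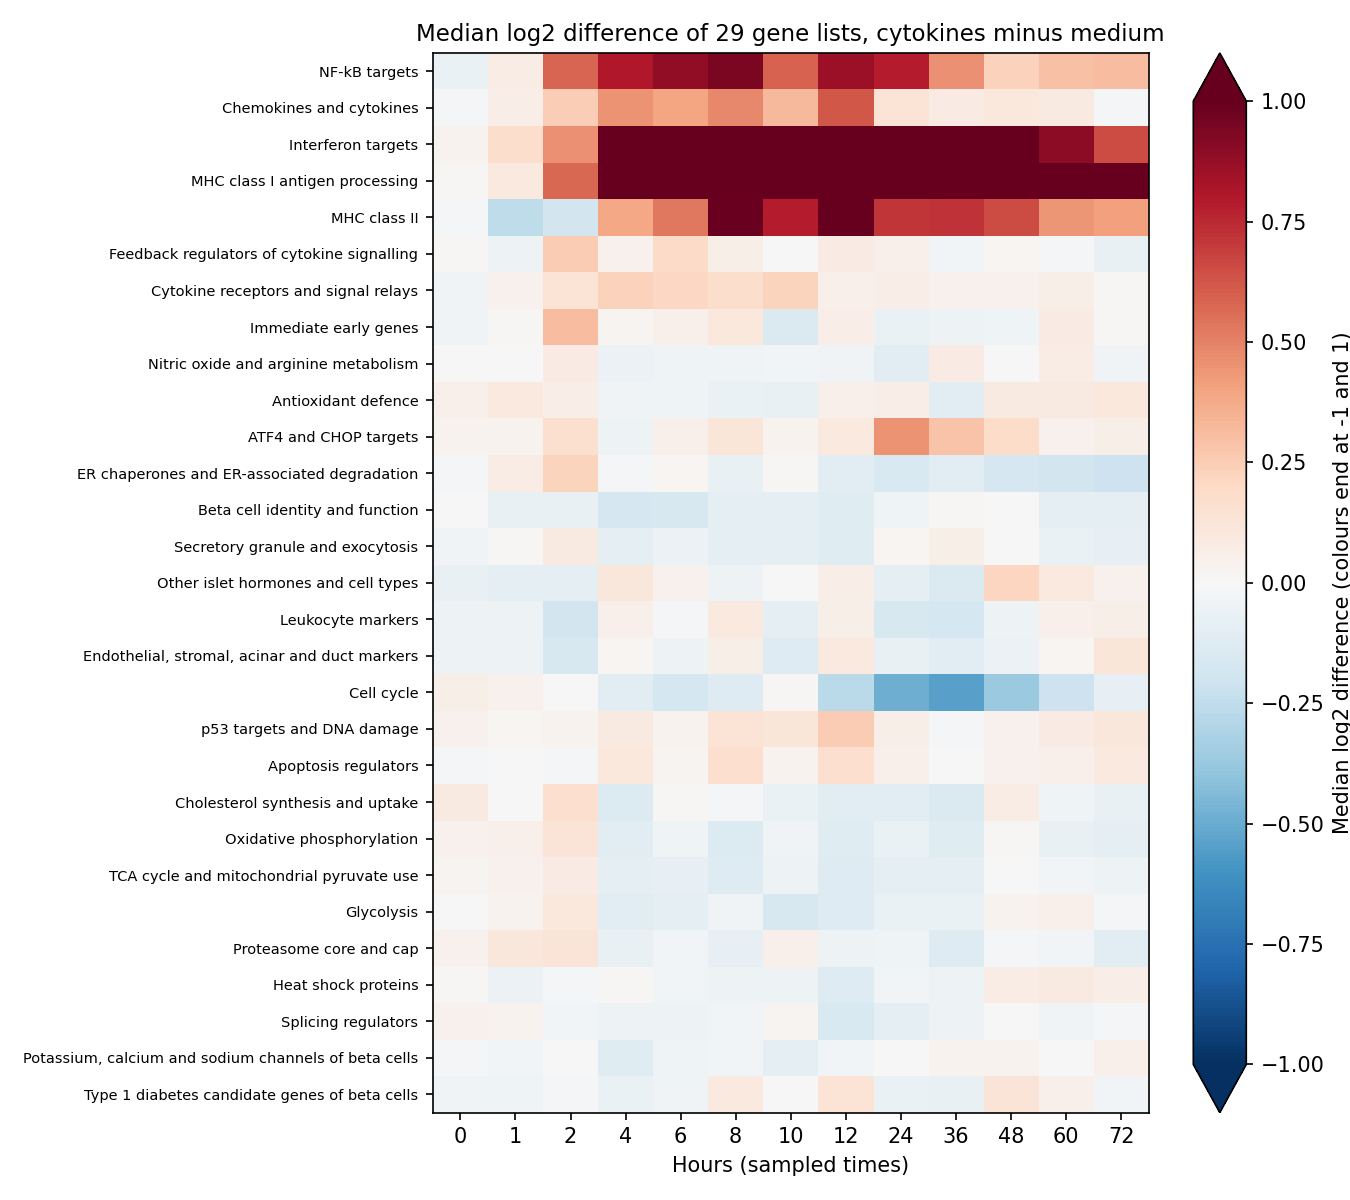
Median log2 difference, cytokine minus control, of each of the 29 gene lists (vertical axis) at each of the 13 sampled times in hours (horizontal axis), with colours that end at -1 and 1. Interferon targets have a median of 2.55 over the intermediate window, and the cell cycle list one of -0.38 over the late window.

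The difference between the late and the early cytokine effect was tested directly. Cd74 differed more late than early, by 4.59 (SE 0.458, limma adjusted p = 6.66e-06), as did RT1-Da, by 3.03 (adjusted p = 0.00355), and Psmb9, by 1.75 (adjusted p = 0.00574). Gcg, at -3.00 (adjusted p = 1.67e-07), Cxcl1, at -2.31 (4.69e-07, and 0.199 with replicate 1 arrays alone), and Ins2, at -0.70 (0.000718), went the other way. In all, 218 genes were called, 108 more positive and 110 more negative late. Against these, 97 were called without control 2 h, 129 with replicate 1 arrays alone and 415 with the replicate number as a block. MHC class I processing was shifted up (9 of 17 more positive, 13 adjusted over the list alone, camera adjusted p = 6.37e-21), as was MHC class II (6 of 12, 8 alone, 1.04e-12), each with adjusted p = 0.0522 with an estimated correlation. Chemokines and cytokines were shifted down (1 of 34 more positive and 6 more negative, 1 and 12 alone, camera adjusted p = 2.12e-09), with adjusted p = 0.0178 with an estimated correlation.

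Culture time without cytokines was followed in the control arrays, 5 late times against 2 arrays at 0 h. Stard5, a sterol transfer protein gene, rose by 0.81 (SE 0.103, limma adjusted p = 0.00246) and was the only gene called here of 1938 with an unadjusted p under 0.05. Ins2 differed by 0.14 (adjusted p = 0.603) and Gcg by -0.15 (adjusted p = 0.817). Without control 0 h replicate 1 limma called 0 genes, and Stard5 had an adjusted p of 0.387. Without control 0 h replicate 2 it called 653, 273 higher and 380 lower, and without control 72 h it called 2. On the second principal component, control 0 h replicate 1 lay at 8.68 and replicate 2 at -2.42. The late control arrays lay between -11.3 and -1.64 on it, so the single call does not show that control cells hardly changed. The additive model called 0, with an adjusted p of 0.0842 for Stard5, the replicate number as a block gave 29, and replicate 1 arrays alone gave 963. Lists of the cell cycle (camera adjusted p = 0.000751), antioxidant defence (0.00134), the proteasome (0.00134), receptors and relays (0.00795) and immediate early genes (0.00847) were shifted down. In the same order they had adjusted p = 0.718, 0.718, 0.718, 0.128 and 0.514 with an estimated correlation. limma called 0 of their members, with 11, 9, 7, 3 and 4 at an unadjusted p under 0.05, and adjusted over the list alone 4 antioxidant genes were lower.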

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

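The test of a loss of glucagon cells and the adjustment of the permutation tests over all lists were chosen after the results were seen, while the tests of a single aberrant array and of the ER lists were written before their own values were known, on lists whose shifts had been seen.

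The cytokine difference changed between the early and the late window for 218 genes by limma's test of the difference itself (97 without control 2 h, 415 with the replicate number as a block). The largest gains were those of Cd74 (4.59), RT1-Da (3.03), Serpina1 (2.28), a protease inhibitor gene, Mx2 (2.20), and the immunoproteasome genes Psmb8 (1.77) and Psmb9 (1.75) on the log2 scale. Mx2 did not pass without control 2 h (log2 1.22, adjusted p = 0.495), control 24 h (0.134), control 36 h (0.0763), control 1 h replicate 1 (0.0521), cytokine 1 h replicate 2 (0.0557), cytokine 2 h replicate 2 (0.0613) or cytokine 4 h replicate 1 (0.0586), and without control 4 h its value was 4.06. Nor did it pass with trend and robust moderation (adjusted p = 0.0679), in the additive model (0.285) or with replicate 1 arrays alone (0.291). The largest losses were those of Gcg (-3.00), Cxcl1 (-2.31), Cxcl9 (-2.18), Car8 (-2.02), Igf1 (-1.88) and Gda (-1.65), a purine enzyme gene that was not called without control 4 h (log2 -0.89, adjusted p = 0.19), in the additive model (0.0957) or with replicate 1 arrays alone (0.423). With replicate 1 arrays alone, Cxcl1 (adjusted p = 0.199) and Cxcl9 (0.217) did not pass either. Among the genes named beforehand, Irf1 differed by -1.60 (adjusted p = 0.0044), Ccl2 by -1.29 (0.000448) and Ins2 by -0.70 (0.000718).

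Among the lists, the median of this late minus early difference was 1.00 for MHC class I processing, 0.59 for MHC class II and -0.21 for chemokines and cytokines. With an estimated correlation camera gave adjusted p = 0.0522 for each MHC list and 0.0178 for chemokines and cytokines. ATF4 and CHOP targets were shifted up, with a median of 0.16 (camera adjusted p = 3.52e-05, and adjusted p = 0.27 with an estimated correlation). ER chaperones (median -0.19, 1.83e-10, and adjusted p = 0.27 with an estimated correlation), the cell cycle (-0.29, 2.74e-12, and 0.133 likewise) and immediate early genes (-0.18, 0.00338, and 0.172) were shifted down. Smaller downward medians were those of oxidative phosphorylation (-0.092, 0.000478, and adjusted p = 0.494 with an estimated correlation), the TCA cycle (-0.093, 0.0208, and 0.498) and the proteasome (-0.081, 0.0251, and 0.581). Of the 2647 unnamed probe sets, tested apart, limma called 16 in the early, 92 in the intermediate and 84 in the late window, against 0 at 0 h, where 98 had an unadjusted p under 0.05.

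The late fall of Gcg in an insulin-producing line is a pattern with 3 explanations. A single aberrant array is argued against, since the late difference stayed between -2.92 and -2.71 with each of the 15 arrays left out. A loss of glucagon cells from a mixed culture stays open. Of the other alpha cell genes fixed beforehand, only Irx2 lay above the median gene level of 6.77, and its late difference was -0.15 (adjusted p = 0.463), while Irx1 (0.05) and Ttr (0.24) were dim. The difference of Irx2 was far smaller than such a loss would need, but this rests on 1 gene near that level. Lower glucagon transcription in the cells themselves, as a response to the cytokines, may also account for the fall and was not tested.

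Averaged over the late window, ER chaperone and degradation genes were lower while ATF4 and CHOP targets were higher, although the shift of neither list was called with an estimated correlation (adjusted p = 0.468 and 0.0615). At single times the ATF4 and CHOP median fell from 0.448 at 24 h to 0.041 at 60 h and 0.062 at 72 h. The ER median was -0.152, -0.186 and -0.205 at these times. Variation between arrays that is unrelated to their labels is argued against. Regrouping the arrays does not exclude an effect of the replicate number. All late control arrays are replicate 1, while the late cytokine arrays carry both numbers. Neither late list call was lost with the replicate number as a block. Other lists, some of them not called late by camera, also passed the permutation test given next, so passing it is not particular to these lists. The ER list mean was 9.86 ± 0.10 (SD, n = 5) in control and 9.65 ± 0.065 (SD, n = 10) in cytokine arrays, with an exact two-sided permutation p of 0.000666 over 3003 splits (0.00215 with Benjamini-Hochberg adjustment over all 29 lists), and the ATF4 and CHOP list differed by 0.24 (exact permutation p = 0.00766, adjusted 0.0159). Lower readings of bright genes in general would not account for the size of the ER shift. The ER median was -0.18, at percentile 0 of 10000 random lists matched on level, whose median was -0.0146 and central range -0.066 to 0.040. Those lists draw genes independently, while the ER list has an estimated inter-gene correlation of 0.418 and was taken up after its fall was seen. The percentile therefore does not gauge chance, and no biological explanation was tested.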

How the results depend on the processing

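The alternatives without 4 h and without 36 h were chosen after seeing the data, and the others before. Beside the counts named here, all totals of called genes (both directions together) stayed within 1.5 times of the reported ones, quantile normalization, centring on medians, the filter on dim genes, the mean of all probe sets, trend and robust moderation and array weights included. No scaling moved the share of higher calls by over 10 percentage points. The additive model on the arrays of a comparison called 45 genes early (36 at least 2-fold) and 0 for culture time, and replicate 1 arrays alone called 20 early (20 at least 2-fold), 988 in the intermediate window (637 higher and 351 lower), 129 for late minus early and 963 for culture time. Both fits have fewer arrays. The latter could not be fitted at 0 h, where no residual degrees of freedom remain. At least 2-fold, replicate 1 arrays alone gave 151 higher and 25 lower genes late. Without 4 h, 96 genes were called early (50 at least 2-fold), and without 36 h 581 genes were higher and 403 lower late. Of 39 list shifts in the 3 windows, 24 were called with an estimated correlation, and 34 with fry, 29 of them the same.

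With 1 array left out, counts ranged from 0 to 92 at 0 h, from 96 to 352 early (50 to 92 at least 2-fold), from 97 to 255 for late minus early, and from 0 to 653 for culture time. They ranged from 1027 to 1498 in the intermediate window (224 to 240 at least 2-fold) and from 977 to 1506 in the late window (131 to 157). Values that turned sign were those of Ins1 early with quantile normalization (-1.744e-15, since the brightest probe set gets the same value on every array), Ccl2 late with quantile normalization (0.0155) and with single arrays left out (-0.0680 to 0.0330), Ifih1 early without 4 h (-0.0458) and with single arrays left out (-0.0458 to 0.846), and Slc2a2 early (0.0295, and -0.111 to 0.0295). Of these only Ifih1 was called. Its differences at single times were -0.11 at 1 h, 0.02 at 2 h and 1.80 at 4 h, so its early value came from 4 h. For Ccl2 the cause was not tested. Among the named genes, 86 calls were lost with replicate 1 arrays alone, 44 in the additive model, 20 without 4 h besides that of Ifih1, 16 without control 2 h, 14 without control 24 h and 12 without 36 h.

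The replicate number as a block gave 415 genes for late minus early and 29 for culture time, against 218 and 1. Its totals in the windows were within 1.5 times, but not each direction. It gave 292 higher and 26 lower genes early, 931 and 1034 in the intermediate window and 837 and 943 in the late window. Of the named-gene calls 2 did not pass with it, among them Ins1 late (log2 -0.24, adjusted p = 0.06), and of the 39 list calls 4 did not, namely ER chaperones (adjusted p = 0.127) and p53 targets (0.0549) early and oxidative phosphorylation in the intermediate (0.0841) and late (0.258) windows. Same-numbered arrays did not deviate together in every pair of groups (r over 0.1 in 68 of 91 pairs, median 0.206, from -0.172 to 0.432), so the numbers were not taken to pair the arrays in the reported fit. This strict rule does not show that the arrays are unpaired, as only 7 of the 91 pairs had r under 0. The median r with other groups was lowest for cytokine 4 h (0.0028) and cytokine 6 h (0.065). In the remaining groups it lay between 0.162 and 0.266, so the lack of pairing was not general. Same-numbered arrays did share something in most groups. The mean r with the other groups was above 0 in 14 of 14 groups. On the second principal component (12.5% of the variance) replicate 2 lay lower than replicate 1 in 13 of 14, all but cytokine 4 h. The cause was not tested. Every control array after 1 h is labelled replicate 1, while cytokine arrays at most times carry both numbers. The replicate number is thus partly tied to treatment in each window. The reported fit does not separate a shared replicate effect from the cytokine difference, so the blocked counts stand beside the reported ones. Signal over background is not known for these arrays, which limits what can be said of dim genes.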

Other observations

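Tests of a baseline difference between replicates were chosen after the result was seen, and those of a compressed range and of regrouped arrays before, although the criteria for the baseline difference and for the compressed range were altered once their values were known.

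Single genes followed distinct courses under the cytokines. Mx2 differed by 0.16 at 1 h and 0.00 at 2 h, then by 5.68 at 4 h, 6.89 at 10 h and 2.80 at 72 h on the log2 scale. Cd74 differed by -0.27 at 2 h, 2.00 at 4 h and 5.57 at 48 h. Ccl2 differed by 2.52 at 4 h and -0.26 at 72 h, and Cxcl1 by 5.20 at 12 h and 0.81 at 72 h. Ddit3 differed by 1.63 at 24 h, 1.73 at 36 h and 0.21 at 72 h, and Ins2 by -0.33 at 24 h and -0.83 at 72 h. These are values of single times, without calls.

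At all 5 late times the genes called higher late were lower in cytokine replicate 2 than in replicate 1, by a median of 0.0448 to 0.141 over 748 genes, and single genes chosen after their values were seen differed more, such as Mx2 at 72 h (8.52 against 6.68) and Cd74 (11.03 against 9.60). Of the 748 genes 421 to 549 were lower in replicate 2, and Cxcl10 was higher there at 48 h (9.22 against 9.37) and 72 h (8.96 against 9.19). A compressed signal range in replicate 2 is argued against, since the spread of 14225 uncalled genes was not lower there but wider at 5 of 5 late times (-2.97 to -0.462% lower). The cytokine difference was lower in replicate 2 by 17.3% at 36 h and 15.2% at 48 h, but by only 4.07% at 60 h and 0.0986% at 72 h. The bound set beforehand was not met at 24 h, where the difference was not lower (-2.29%), so the argument against a compressed range rests on the spread being wider. A difference between replicates before exposure stays open as a possible explanation: the gap was -0.107 to 0.00367 in the 3 unexposed groups, and the margin of 0.0411 to the lowest late gap (0.0448) is smaller than their SD of 0.0572, and a replicate-specific response was not tested.

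Other splits of the arrays of each comparison were refitted with the additive model, 100 splits each with the real one included. Chance assignment of arrays can be excluded at a share under 0.05 for the intermediate window (1 of 100 splits gave as many genes as the real 1422, highest other 1) and the late window (1 of 100, 1780 and 1). For late minus early the values were 1 of 100, 224 and 32. There the labels were reassigned within both windows, which also breaks up the cytokine difference itself. These splits therefore cannot exclude chance for the change between windows. For the early window 3 of 100 splits gave as many as the real 45, and the highest other gave 137. That split set the 4 cytokine arrays at 2 and 4 h against the other early arrays. As the model includes time, it compares control with cytokine arrays at 2 and 4 h with the sign turned. The other such split set control and cytokine arrays at 2 h and control 4 h against the rest, which leaves the cytokine difference at 4 h alone. Both therefore hold the real difference at part of the times and do not show what chance gives.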
